A study of Mus musculus with 9 samples.

How the data were processed

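Gene expression was measured in medullary thymic epithelial cells that carry CD80 on their surface, taken from female Balb/c mice 4 to 6 weeks old. The 9 arrays fall into 3 groups of 3, namely wild type (replicates 1 to 3), C2TA knockdown (replicates 4 to 6) and C2TA knockout (replicates 7 to 9). The grouping was taken from the sample titles. The labels call the samples of a group biological replicates and do not say how many mice stand behind each, so p-values measure the spread between these samples.

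Per the labels' protocols, total RNA was isolated with a column kit that also retains small RNA and was labelled with biotin. The deposited values are on the log2 scale and were made with RMA, per the submitters' processing notes, a method that corrects background, normalizes between arrays and summarises the probes of each probe set by median polish. The software version, the genome build and the annotation release behind the array are not given in the sources used here. A second copy of the log2 values was also deposited, and on each of the 9 arrays all 35552 of its values were identical to those used here. Intensity values on a linear scale were deposited as well. These intensities were made with RMA before deposit, per the file headers, and were not tested. The authors' deposited table further holds a q-value in percent per probe set, a score that reaches 114, and does not state which groups it compares. It was used only for description.

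The table holds 35552 probe sets. Of these, 21536 have 1 gene symbol, 0 have several and 14016 have none. Symbols were updated through the mouse RefSeq gene table of assembly GRCm38.p6, which named 15192 probe sets by accession, 3746 by symbol and 1262 by synonym, and 1336 kept the symbol of the file. That table served only for names and for the order of neighbouring genes, and no position is printed. For each of the 19593 genes the probe set with the highest mean over all arrays was kept, a choice that concerned the 938 genes with more than 1 probe set. No gene was left out for a low level.

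One linear model over all 9 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 6 residual degrees of freedom. Its contrasts were knockdown against wild type, knockout against wild type and knockdown against knockout. P-values are two-sided, were adjusted by the Benjamini-Hochberg method over all genes, and passed at 0.05. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1. Before the data were examined, 21 gene lists were fixed, of which 20 were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. The other list holds sex-linked genes and served as a check of the labels. Camera with an estimated correlation and fry were run as alternatives.

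The rule for naming genes was also fixed before the data were examined. It takes Ciita, all measured MHC class II genes, up to 10 genes per direction with the largest changes past the threshold and without overlap between groups, genes with the smallest p to fill a direction up to 5, and from each other list the members past the threshold or otherwise the 2 with the smallest p. Other members given as examples of a list were chosen after their values were seen. One gene that the rule names is not reported here, though the counts include it. The alternatives were a repeated quantile normalization, centring on the array median, 2 filters on dim genes, an intensity trend with and without a robust setting, array weights, a fit of only the groups compared, other choices of probe sets, and leaving out each array in turn. The array weights were estimated gene by gene, because the default estimation did not converge. Leaving out wild type 1 and knockout 7 together and a fit with the interquartile range of each array as a covariate were chosen after seeing the data.

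The fit was tested on simulated data with the means and residual spread of these 19593 genes and 200 changed genes. For knockdown against wild type it recovered 16.4% of genes changed by 0.5 on the log2 scale, 64.2% of those changed by 1 and 97% of those changed by 2, and it also called 11 unchanged genes. The simulated noise was independent between genes and alike on all arrays. Its 200 changed genes also ease the adjusted threshold more than the 13 genes called in the data. These rates may therefore overstate recovery in the data. The number of arrays limits the precision of each value. Median polish gives equal values to several arrays of a probe set, which occurred for 12345 genes, and 525 genes have equal values on all 3 knockdown arrays, so their spread within that group is understated.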

Results

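The data describe sorted medullary thymic epithelial cells, the stromal cells of the thymus that express tissue-restricted antigens and present them to developing T cells. C2TA, whose gene is Ciita, is the transactivator of MHC class II genes. The 3 groups of 3 arrays differ in C2TA, which was intact, silenced or knocked out, and the study asked about the part these cells play themselves in the tolerance of CD4 T cells. The median log2 value of the 9 arrays lay between 4.48 and 4.54. Wild type 1 stood apart, with an interquartile range of 2.20, and knockout 7 came next with 2.37, while the other arrays lay between 2.53 and 2.80.

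Ciita had a log2 level of 6.40 ± 0.14 (SD, n = 3) in wild type, 5.29 ± 0.30 in the knockdown and 6.07 ± 0.10 in the knockout. Its change in the knockdown was -1.11 (SE 0.16), a 2.16-fold lower level in 3 of 3 arrays, which missed the threshold in limma with a Benjamini-Hochberg adjusted p of 0.055. Ciita passed after a repeated quantile normalization, with -1.19 and a limma adjusted p of 0.0138, in a range of 0.00265 to 0.304 over all alternatives. In the knockout the change was -0.33 (SE 0.16), and the probe set may lie outside the deleted part, so this value checks nothing about the knockout label. The Y-linked gene Ddx3y lay at 2.48, 2.26 and 2.34 in the wild type, knockdown and knockout, near the lower end of the scale, in samples labelled female.

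In the knockdown, genes of MHC class II presentation were lower. Aire, the regulator of tissue-restricted antigens in these cells, was higher together with genes that lie next to it. Extra copies of that genomic stretch could raise the Aire value itself, so its rise cannot be assigned to C2TA silencing. H2-DMb2 was 4.01-fold lower (95% interval of the log2 change -2.54 to -1.47) and H2-Oa fell by 1.96 (SE 0.18, 3.88-fold), both subunits of the chaperones that control peptide loading of class II molecules. H2-DMa fell by 1.49 (SE 0.14). Aire rose by 1.54 (SE 0.14), a 2.92-fold higher level, and its neighbour Pfkl, a phosphofructokinase of glycolysis, rose by 2.31 (SE 0.20, 4.97-fold). Krt1, a keratin of the suprabasal epidermis, rose by 1.77 (SE 0.16).

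The comparison of knockdown and wild type called 13 of 19593 genes in limma at a Benjamini-Hochberg adjusted p of 0.05, 9 higher and 4 lower. Over all genes, the arrays of both groups did not overlap in 8.25%, where chance gives 10%. The 9 higher genes were Pfkl, Pwp2, Gatd3a, Krt1, Aire, Cfap410, Teddm3, Krt79 and Rdh9. Gatd3a, Cfap410 and Teddm3 are named D10Jhu81e, 1810043G02Rik and 2310042E22Rik on the array. Krt79 rose by 1.10 (SE 0.11) and Rdh9, of the retinol dehydrogenase family, by 0.97 (SE 0.12).

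All 8 measured members of the MHC class II list had lower means in the knockdown, with a median change of -1.46. Of these, 3 passed over all genes, and 8 passed adjusted over the list alone. The number past the threshold over all genes was 8 after a repeated quantile normalization, with array weights and without wild type 1, and 7 and 5 under the filters on dim genes. It was 0 in a fit of only the 2 groups compared, 1 without knockdown 6 and 2 without any 1 of the other arrays. The 5 others had limma adjusted p-values between 0.055 and 0.332, among them H2-Ab1 with -1.51 (SE 0.22), H2-Aa with -1.44 (SE 0.21) and Cd74, the invariant chain, with -1.24 (SE 0.19). H2-Eb1 had -0.96 (SE 0.21), and its 3 knockdown arrays hold an equal value, a product of the summary by RMA. The list was lower in camera with an adjusted p of 1.59e-28, and adjusted p = 0.0107 with an estimated correlation. H2-DMb2 has a near-identical copy, H2-DMb1, so its value is uncertain as to the gene.

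**Figure D1:**
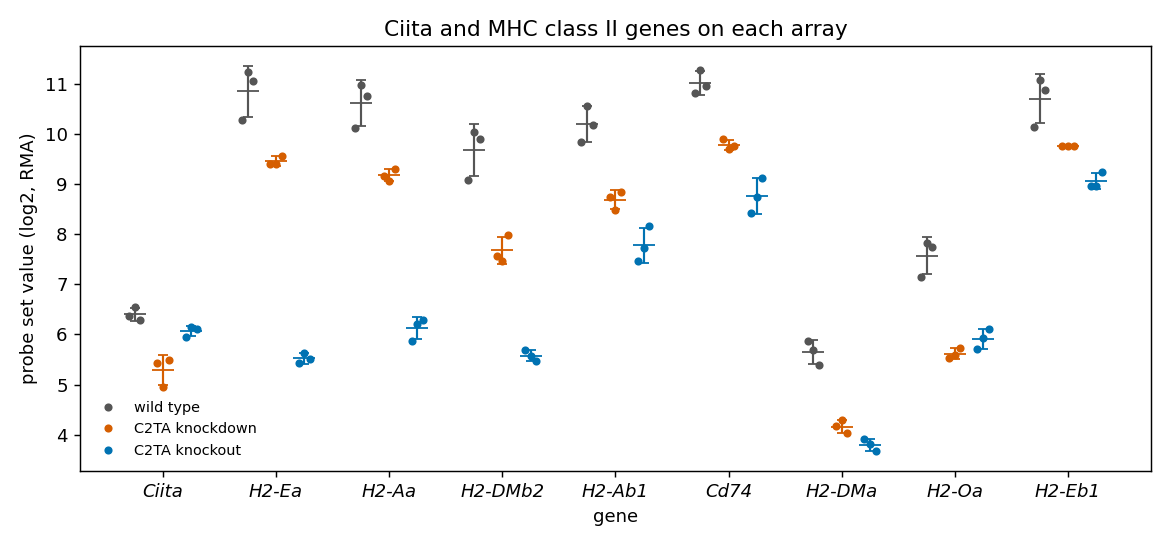
Log2 values of Ciita and the 8 measured MHC class II genes on each of the 9 arrays. Points are arrays, horizontal marks are group means and bars are SDs (n = 3). The knockdown lies between wild type and knockout for H2-Ea, H2-Aa and H2-DMb2, with means of 9.46, 9.18 and 7.68.

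Among the 11 measured neighbours of Aire on the list, 10 had higher means. Of the 11, 4 passed over all genes, and the same 4 passed adjusted over the list alone. These were Pfkl, Pwp2 with 2.06 (SE 0.12), Gatd3a with 1.87 (SE 0.15) and Cfap410 with 1.43 (SE 0.18). In the order of measured genes, Cfap410 and Pfkl precede Aire, and Dnmt3l, Icosl, Gatd3a and Pwp2 follow it. Dnmt3l had a change of 0.47 (SE 0.23) and Icosl, a costimulatory ligand, one of -0.45 (SE 0.22), and neither passed. The next genes on either side, Trpm2 with 0.02 (SE 0.18) and Trappc10 with 0.01 (SE 0.14), did not pass either. The list of Aire neighbours had a median of 0.34, and 0.17 without wild type 1. It was higher in camera with an adjusted p of 3.2e-10, and adjusted p = 0.0107 with an estimated correlation.

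**Figure D2:**
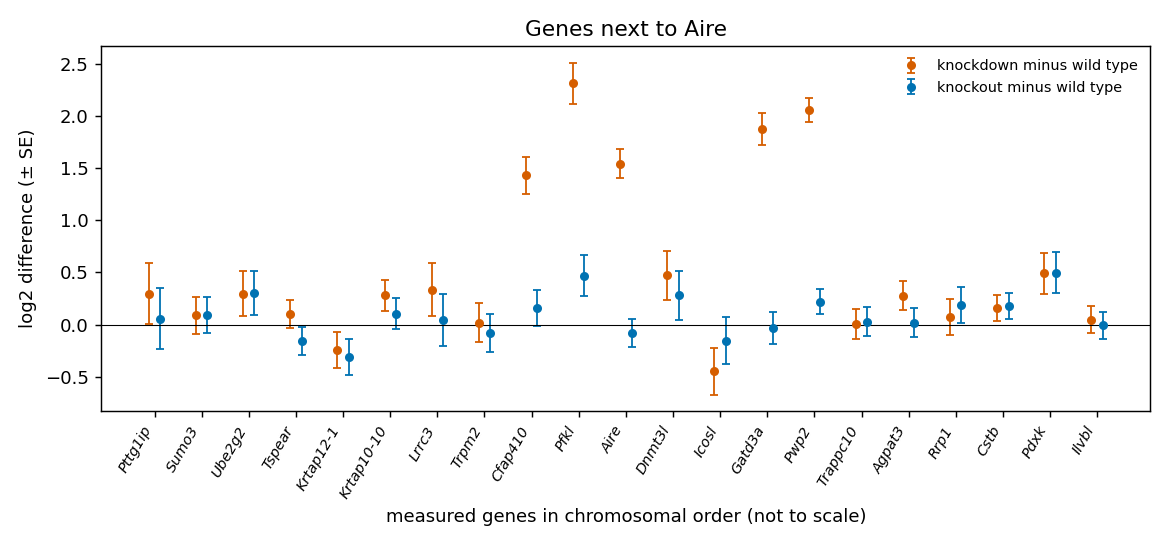
Log2 difference from wild type, with its standard error, for Aire and the 10 measured genes on each side in chromosomal order. Orange points are the knockdown and blue points the knockout (n = 3 per group). Pfkl reaches 2.31 and Pwp2 2.06 in the knockdown, while Icosl between them lies at -0.45.

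Cornified and tuft-like epithelial genes had a median change of 0.28 in the knockdown, with 12 of 14 members higher. Krt1 passed over all genes, and Krt1, Krt10, Krtdap and Lor passed adjusted over the list alone. Krt10, the partner keratin of Krt1, had 0.87 and loricrin (Lor), a protein of the cornified envelope, had 0.54. Camera gave the list an adjusted p of 9.59e-08, and adjusted p = 0.279 with an estimated correlation. The median was 0.18 without wild type 1 and 0.45 without wild type 3. Dendritic cell and macrophage markers had a median of -0.19, with 18 of 20 members lower and 0 past the threshold over all genes or adjusted over the list alone. Camera gave an adjusted p of 0.000181, and adjusted p = 0.357 with an estimated correlation. Ccr7, a chemokine receptor of migrating dendritic cells, had -0.76 (SE 0.22).

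In the knockdown, Aire was the member of the mature epithelial list that passed, while Ccl22, a chemokine of these cells, had -1.27 and passed adjusted over the list alone. The Aire-dependent antigens had a median of -0.08, with 8 members higher and 9 lower. Of these, 0 passed over all genes, and Apoa4, an apolipoprotein with -0.84 (SE 0.13), passed adjusted over the list alone. Camera called both lists lower, with adjusted p-values of 0.0286 and 0.042. These calls were lost, with adjusted p = 0.689 and adjusted p = 0.377 with an estimated correlation. Single arrays ended them as well, namely wild type 2 or 3 or knockdown 5 for both, knockdown 6 for the mature list, and knockdown 4 or knockout 7 for the Aire-dependent list. The mature median of -0.09 was -0.20 without wild type 1, 0.0013 without wild type 2 and -0.056 without knockdown 5. The Aire-dependent median was -0.019 without wild type 2, -0.14 without wild type 3, -0.053 without knockdown 4 and -0.022 without knockdown 5.

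The count for the knockdown was 48 without wild type 1, 12 higher and 36 lower. It was 47 after a repeated quantile normalization, 18 higher and 29 lower, and array weights gave 163 higher and 248 lower. The count was 8 without knockdown 4, 5 without knockdown 6 and 2 in a fit of only the 2 groups compared, each with more higher than lower genes. H2-DMb2 and Rdh9 missed the threshold without any 1 of the 8 arrays other than wild type 1, Cfap410 and Teddm3 without most of them, and H2-DMa, Krt1 and Krt79 without knockdown 6 (limma adjusted p of 0.0505).

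In the knockout, all 8 measured MHC class II genes fell. H2-Ea fell by 5.34 on the log2 scale (SE 0.22, 40.4-fold), H2-Aa fell by 4.50 (SE 0.21, 22.6-fold) and H2-DMb2 fell by 4.10 (SE 0.24, 17.2-fold). H2-Ab1 fell by 2.42 (SE 0.22) and Cd74 fell by 2.26 (SE 0.19). H2-DMa, H2-Oa and H2-Eb1 had smaller changes of -1.85, -1.67 and -1.65. Krt6b, a keratin of stressed epithelium, rose by 0.86 (SE 0.10), and Aire had a change of -0.08 (SE 0.14).

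These were the 9 genes called in limma at a Benjamini-Hochberg adjusted p of 0.05, 1 higher and 8 lower. The class II list had a median of -2.34, a camera adjusted p of 3.67e-52, and adjusted p = 0.0041 with an estimated correlation. All 8 members also passed adjusted over the list alone. The genes with the next smallest p among those with higher means did not pass. They were Slc15a2, a peptide transporter with 0.82 (SE 0.13), Ccna2, or cyclin A2, with 1.01 (SE 0.19), Gpr183 (Ebi2 on the array), a receptor that guides immune cells, with 0.63 (SE 0.12), and Cdca7 with 0.68 (SE 0.15).

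All 23 measured cell cycle genes had higher means in the knockout, with a median of 0.53. Of these, 0 passed over all genes and 9 passed adjusted over the list alone, among them Top2a with 0.97, Mcm3 with 0.78 (SE 0.19) and Cdk1 with 0.58. Camera gave an adjusted p of 3.4e-20, and adjusted p = 0.315 with an estimated correlation. Thymocyte markers moved beside them, with a median of 0.48, 17 of 19 members higher and 0 past the threshold over all genes or adjusted over the list alone. Camera gave an adjusted p of 1.89e-09, and adjusted p = 0.496 with an estimated correlation. Rag1, which cuts DNA in antigen receptor rearrangement, had 1.10 (SE 0.34). Both lists stood highest on knockout 8, at 0.76 for cell cycle and 0.72 for thymocytes relative to the mean of the 9 arrays, then on knockout 9, at 0.21 and 0.41, and knockout 7 lay at -0.006 and -0.20. Dendritic cell and macrophage markers lay at 0.31 on knockout 8, 0.39 on knockout 9 and -0.19 on knockout 7. Without knockout 8 the medians were 0.32 and 0.25, and without knockout 7 the thymocyte median was 0.73.

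**Figure D3:**
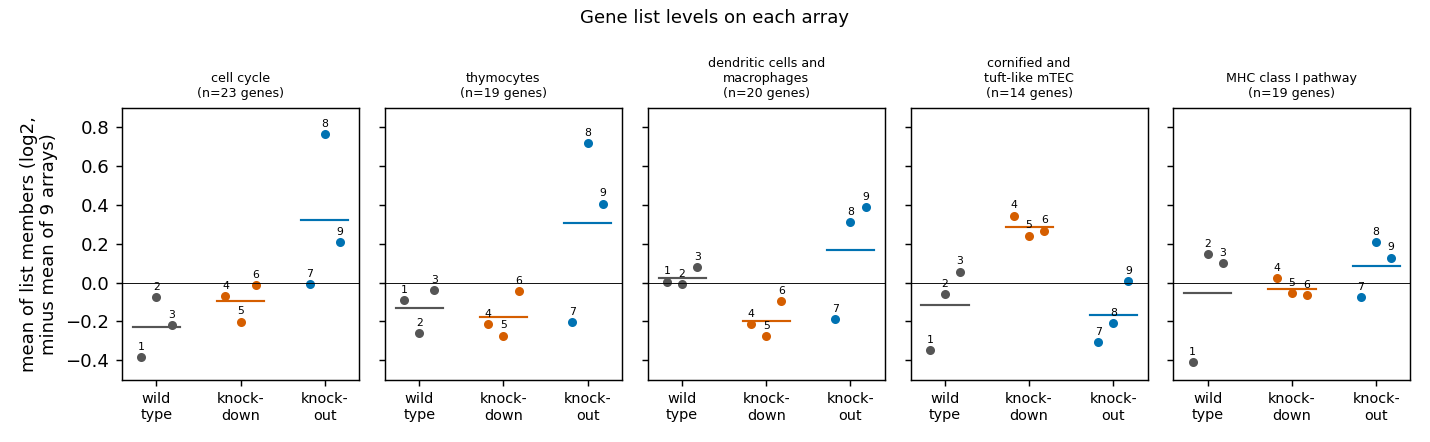
Mean log2 level of 5 gene lists on each array, relative to the mean of the 9 arrays. Points carry the replicate number and lines are group means (n = 3). Knockout 8 reaches 0.76 for cell cycle genes and 0.72 for thymocyte markers, and the 3 knockdown arrays lie between 0.24 and 0.34 for cornified and tuft-like genes.

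Interferon response genes had a median of 0.15 in the knockout, MHC class I genes 0.16 and immature epithelial genes 0.18, and immediate early genes had -0.16. Camera called these lists, and the calls were lost, with adjusted p = 0.588 with an estimated correlation for each. Gbp2, an interferon-induced GTPase, was 2.0-fold higher (SE 0.30 on the log2 scale) and Cxcl9, an interferon-induced chemokine, had 0.82 (SE 0.21), and neither passed. Without wild type 1 the medians of the MHC class I, interferon and immature epithelial lists were 0.023, 0.029 and 0.054, and the camera calls were lost. The MHC class I median was 0.25 without wild type 2, and its call was lost without knockout 8 or 9, with 0.063 and 0.12. The interferon median was 0.28 without wild type 3 and 0.26 without knockout 7, and its call was lost at 0.07 without knockout 9. Immature epithelial genes lost theirs without knockout 8 or 9, with 0.16 and 0.14. Immediate early genes lost theirs without wild type 2, with -0.032, and without knockout 7, with -0.13, and had -0.26 without wild type 3 and -0.10 without knockout 8.

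Among the 9 genes of the knockout, H2-Eb1, H2-Oa and Krt6b missed the threshold without any 1 of the 8 arrays other than wild type 1, with limma adjusted p-values up to 0.316, 0.137 and 0.193. H2-Eb1 also missed it with centring on the array median and with an intensity trend, and 4 genes passed in a fit of only the 2 groups compared.

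Set against the knockout directly, the knockdown had higher levels of H2-Ea, H2-Aa and H2-DMb2, of Aire and of Aire neighbours. H2-Ea was higher by 3.94 (SE 0.22, 15.4-fold), H2-Aa by 3.05 (SE 0.21, 8.31-fold) and H2-DMb2 by 2.10 (SE 0.24). Gatd3a was higher by 1.90 (SE 0.15), Pfkl and Pwp2 each by 1.84, Aire by 1.62 (SE 0.14) and Krt1 by 1.52 (SE 0.16). H2-Oa had a difference of -0.29 (SE 0.18), and H2-DMa one of 0.36 (SE 0.14), and neither passed.

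These 8 higher genes and 0 lower genes passed in limma at a Benjamini-Hochberg adjusted p of 0.05. At an unadjusted limma p under 0.05 there were 553 higher and 435 lower genes. Their total is close to what chance gives at that threshold over 19593 genes. The arrays of both groups did not overlap in 9.6% of genes, where chance gives 10%. Ciita itself had a difference of -0.78 (SE 0.16), with a limma adjusted p of 0.237. The class II list had a median difference of 0.97, with 7 of 8 members higher, of which 3 passed over all genes and 7 adjusted over the list alone. Camera gave an adjusted p of 4.59e-18, and adjusted p = 0.0346 with an estimated correlation. The list of Aire neighbours had a median of 0.26, with 3 members past the threshold over all genes and 4 adjusted over the list alone, and adjusted p = 0.0129 with an estimated correlation.

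All 14 cornified and tuft-like genes had higher means in the knockdown than in the knockout, with a median of 0.35, of which 1 passed over all genes and 5 adjusted over the list alone. The list had adjusted p = 0.116 with an estimated correlation. Dclk1, a marker of tuft cells, had 0.98. Cell cycle genes had a median of -0.39, thymocyte markers -0.49, and dendritic cell and macrophage markers -0.33. Camera called these lists lower, and the calls were lost, with adjusted p = 0.198 with an estimated correlation for each of the first pair and adjusted p = 0.116 with an estimated correlation for the last. Without knockout 8 the cell cycle and thymocyte medians were -0.16 and -0.25, and without knockout 7 the thymocyte and dendritic cell medians were -0.75 and -0.51. Adjusted over the list alone, 3, 0 and 1 of their members passed. Lower genes with the smallest p that did not pass were Lypd8 (2210415F13Rik on the array) with -1.39 (SE 0.20), Chga, or chromogranin A of neuroendocrine cells, with -1.01 (SE 0.15), Muc3, an intestinal mucin, with -0.78 (SE 0.12), Gpr183 with -0.77 (SE 0.12) and Slc39a4, a zinc transporter, with -0.71 (SE 0.12).

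Immediate early and heat shock genes, which respond to stress and handling of cells, had a median of 0.19 in the knockdown relative to the knockout, with 19 of 23 members higher and 0 past the threshold over all genes or adjusted over the list alone. Camera gave an adjusted p of 1.62e-05, and adjusted p = 0.346 with an estimated correlation. The median was 0.12 without knockdown 5 or knockout 8 and 0.29 without knockout 9, and the camera call was lost with array weights (adjusted p of 0.0553) and without both wild type 1 and knockout 7 (adjusted p of 0.0688). Camera also called 5 lists lower, namely NF-kB targets with a median of -0.14, MHC class I genes with -0.10, mature epithelial genes with -0.09, although Aire on that list was higher, stromal genes with -0.09 and partner factors of C2TA with -0.053. These calls were lost, with adjusted p = 0.651, 0.654, 0.730, 0.116 and 0.473 with an estimated correlation. No member was lower past the threshold over all genes or adjusted over the list alone. Leaving out single arrays ended these calls as well. NF-kB targets lost theirs without knockout 8 or 9, with medians of -0.099 and -0.08, and had -0.082 without knockdown 6. MHC class I genes lost theirs without knockout 8, with -0.094, and had -0.19 without knockout 7. Stromal genes lost theirs without knockout 7, with -0.049. Mature epithelial genes lost theirs without knockdown 5 or 6 or knockout 8 or 9, with -0.078, -0.08, -0.078 and -0.012, and had -0.14 without knockdown 4 and -0.19 without knockout 7. Partner factors lost theirs without knockdown 5 or knockout 8 or 9, with -0.032, -0.12 and -0.074, and had between -0.14 and -0.11 without knockdown 4, knockdown 6 or knockout 7.

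The count between knockdown and knockout was 37 after a repeated quantile normalization, 28 higher and 9 lower, 38 without wild type 1 and 5 without each of knockdown 4, knockdown 6 and knockout 7. H2-DMb2 missed the threshold without any 1 knockdown or knockout array, Pfkl without any but knockout 8, and Krt1 without knockdown 4 or 6 or knockout 7 or 8.

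Genes lower in both the knockdown and the knockout against wild type were H2-DMa, H2-DMb2 and H2-Oa, 3 genes. Independent lists would share 0.00163, a value that leaves out the shared wild-type arrays, and 100 simulations of unchanged groups with shared controls gave a mean of 0, which leaves out the effects. The higher genes shared 0. Krt6b, the only gene called higher in the knockout, also lay above wild type in the knockdown without passing. Its knockdown arrays held 5.20 to 5.29, against 4.51 to 4.55 in wild type. Part of any excess in the overlap may come from the shared controls, which are too few to be split. Across genes, which are not independent replicates, the changes of knockdown and knockout correlated with Pearson's r of 0.524 and Spearman's rho of 0.536. Both share the wild-type arrays, and 100 simulations of unchanged groups gave a mean r of 0.446, with 95% of values from -0.771 to 0.951. The covariance was 0.0204 against a simulated mean of 0.0162, which already holds the shared controls, with 95% of values from -0.0242 to 0.0619. The difference of 0.00418 was -0.00277 without knockout 8 and -0.00126 without knockout 9, and reached 0.0160 without wild type 2.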

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

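The tests of extra copies around Aire and of the higher Aire level were chosen only after the results they measure had been seen. Some probe sets without a gene name, which no comparison above used, passed the threshold. Of 14016, 10 passed in limma at a Benjamini-Hochberg adjusted p of 0.05 between knockdown and knockout, all 10 lower in the knockdown, and 0 passed in either comparison with wild type. Their values form 3 distinct profiles, since 7 of them hold equal values on every array. That profile had means of 5.26 in the knockdown, 6.33 in wild type and 6.79 in the knockout. Equal profiles enter the adjustment as separate tests and make their adjusted p smaller, so the 10 are not separate results.

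Of the 11 listed genes next to Aire, 4 were past the threshold and higher in the knockdown. For the 5 raised genes Aire, Pfkl, Pwp2, Gatd3a and Cfap410, a narrow value range of wild type 1 is argued against as the whole source. Without it and knockout 7 they kept a median of 1.97 against wild type. They were picked for their rise, so this median could hardly fall far. The median of the 11 listed neighbours did fall, from 0.34 to 0.17 without wild type 1. Knockout 7 does not enter these differences, so leaving it out tests nothing here. A sequence shared between the probe sets of the 5 raised genes stays open. Of the 5, 0 carry the mark for cross-hybridisation, but only 108 of 35552 probe sets do. H2-DMb2 lacks it despite a near-identical copy. Extra copies of the genomic stretch around Aire, as a transgene built on that stretch could bring, stay open, and the bound set for them was not passed. The bound counts genes over 20 neighbours whatever their size of change, so it cannot decide on a stretch shorter than that window. The 5 raised genes lie between Trpm2, with 0.02 in the knockdown against wild type, and Trappc10, with 0.01. Among them, Dnmt3l with 0.47 and Icosl with -0.45 did not pass. Of the 20 nearest measured genes, which leave out Aire itself, 4 were higher in limma at p under 0.05 against the knockout. The 99th percentile of other windows is also 4. Against wild type the count was 5 with a percentile of 3. That count includes Pdxk, which had changes of 0.495 in the knockdown and 0.497 in the knockout.

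Cell cycle and thymocyte genes had medians of 0.53 and 0.48 in the knockout, with 0 members past the threshold over all genes, and their camera calls were lost, with adjusted p = 0.315 and adjusted p = 0.496 with an estimated correlation. Without both wild type 1 and knockout 7 the cell cycle median was 0.55. Knockout 7 had the lowest cell cycle level of the knockout arrays, so leaving it out raises the difference and cannot test wild type 1. Without single arrays, wild type 1 among them, the medians ranged from 0.32 to 0.68 for cell cycle and 0.25 to 0.73 for thymocyte genes. These ranges argue against the value range of wild type 1 as the whole source. Thymocytes carried into the knockout preparations may be the source, although a sort for CD80-bearing epithelial cells is meant to exclude them, and the arrays leave this open. On knockout 8 and 9 the thymocyte list lay above its highest wild-type array by 0.76 and 0.44, and on knockout 7 by -0.17, where the cell cycle list was above by 0.07. Of the 19 thymocyte genes, 13 lie above the median level of wild type and 0 stand on another list, the most abundant, Satb1, had a change of 0.61, and dendritic cell and macrophage markers also lay higher on knockout 8 and 9, at 0.31 and 0.39 relative to the mean of the 9 arrays, than on knockout 7, at -0.19.

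Cornified and tuft-like genes had a median of 0.28 in the knockdown, with 12 of 14 members higher and 1 past the threshold over all genes, and adjusted p = 0.279 with an estimated correlation. The range of wild type 1 is argued against as the whole source, since the median was 0.18 without it. Knockout 7 does not enter this difference, so leaving it out tests nothing here. The higher Aire level could be a source, and this stays open, because the Aire-dependent list had a median of -0.082 with members on both sides of 0. That level may itself stem from extra copies of the stretch around Aire. A biological effect of C2TA silencing itself was not tested apart from these.

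Other splits of the 6 arrays of a comparison, with the third group kept, cannot give a share under 0.05, since there are 10 of them. The real split called 13 genes for knockdown against wild type, 9 for knockout against wild type and 8 for knockdown against knockout, and the highest other split called 0 in each, so 1 of the 10 splits gave as many.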

How the results depend on the processing

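Leaving out wild type 1 and knockout 7 together and the interquartile range as a covariate were chosen after seeing the data, and the causes of the shifts below were not tested unless fewer genes or arrays explain them by construction. No paired analysis was possible because the replicate numbers 1 to 9 are unique to single arrays. For knockdown against wild type the 13 genes became 47 after a repeated quantile normalization, 24 without genes below the median level, 22 under a milder filter, 411 with array weights, 2 in a fit of only both groups, 51 without wild type 1 and knockout 7, 144 with the covariate and 5 to 48 without single arrays. For knockout against wild type the 9 became 71 with array weights, 4 in a fit of only both groups, 30 with the covariate and 6 to 13 without single arrays. For knockdown against knockout the 8 became 37 after quantile normalization, 309 with array weights, 18 over all probe sets, 66 without wild type 1 and knockout 7, 155 with the covariate and 5 to 38 without single arrays. The 8 were all higher. Lower genes outnumbered higher ones without wild type 1 and knockout 7 (40 against 26) and with array weights (158 against 151). Over all probe sets 10 were lower and 8 higher, but these are probe sets and not genes. Among probe sets without a gene name, 10 lower ones passed, and they form only 3 distinct profiles. With the covariate 92 were higher and 63 lower. Array weights gave wild type 1 a weight of 0.125 and wild type 3 one of 3.92.

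Ciita passed in knockdown against wild type with -1.19 after quantile normalization, -1.11 under both filters, -0.96 with array weights and -1.15 with the covariate, and it ranged from -1.21 to -0.93 without single arrays. Against the knockout it passed with -0.74 with array weights and -0.79 with the covariate. The class II list kept its direction and call under every alternative run, with medians of -1.69 to -1.29, -2.52 to -2.17 and 0.80 to 1.15 in the order of comparisons above. The lists called by camera numbered 12, 7 and 12, and with an estimated correlation or with fry 2, 1 and 2. Without single arrays they ranged from 7 to 13, 6 to 11 and 8 to 12. The correlation of changes ranged from 0.446 to 0.706 without single arrays. The MHC class I list reversed in the knockdown, to -0.11 with array weights and -0.13 without wild type 1, with or without knockout 7, in a range of -0.13 to 0.12 without single arrays. In the knockout its test turned without wild type 1, at a median of 0.023 in a range up to 0.25. The lysosomal list reversed to -0.18 in the knockdown without wild type 1, with or without knockout 7, and to -0.14 in the knockout, in ranges of -0.18 to 0.14 and -0.14 to 0.17 without single arrays. The immediate early list of the knockout was -0.000623 with array weights, where its test turned. Of 3070 values of named genes under alternatives, 2861 kept their side of the threshold, 95 lost the call and the others gained it. Most belong to genes that did not pass in the fit of all arrays and so had no call to lose. The direction turned in 4 of the values, none of them past the threshold in either fit.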

Other observations

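Lists not described above had these medians in knockdown against wild type. Immature epithelial genes had 0.25 and interferon genes 0.20, with adjusted p = 0.377 and adjusted p = 0.571 with an estimated correlation, and without wild type 1 their medians were 0.13 and 0.09. Camera called both. The interferon call was lost without wild type 1 and with array weights, with camera adjusted p-values of 0.484 and 0.0686. NF-kB targets and cortical epithelial genes each had -0.09, stromal genes -0.08 and neighbours of Ciita 0.10, and camera called all of them, with adjusted p = 0.521, 0.357, 0.249 and 0.411 with an estimated correlation. The NF-kB median was -0.23 without wild type 1 and 0.006 without wild type 2, which ended the call. The cortical call was lost without wild type 2 or 3, at -0.054 and -0.025, and its median was -0.16 without wild type 1. The stromal median was -0.14 without wild type 2 and -0.05 without wild type 3, which ended the call. Neighbours of Ciita lost their call without wild type 1 or 3 or knockdown 5 or 6, at 0.014, 0.14, 0.09 and 0.11, and had 0.16 without wild type 2. With array weights that call was also lost, at 0.044, from a camera adjusted p of 0.0467 with all 9 arrays. MHC class I genes, partner factors of C2TA and B cell genes had 0.01, 0.01 and -0.01, and lysosomal genes 0.06, cell cycle genes 0.12, immediate early genes 0.10, thymocyte genes -0.04 and other tissue-restricted antigens -0.06, none of them called with all 9 arrays. Camera called some of them without a single array. In the order given, the medians without single arrays ranged from -0.13 to 0.12, -0.10 to 0.029, -0.055 to 0.046, -0.18 to 0.14, 0.019 to 0.20, -0.013 to 0.20, -0.12 to 0.0081 and -0.079 to -0.043. Without wild type 1, MHC class I genes had -0.13, lysosomal genes -0.18 and partner factors -0.10, with adjusted p-values of 0.00224, 0.0175 and 0.0378. The cell cycle list was called without wild type 2, knockdown 5 or knockout 8, with medians of 0.20, 0.20 and 0.12 and adjusted p-values of 0.0427, 0.0263 and 0.0244, and its median was 0.019 without wild type 1. Immediate early genes were called without wild type 2 or knockdown 6, at 0.20 and 0.12, and had -0.013 without wild type 3 and 0.01 without knockdown 5.

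In the knockout, dendritic cell markers had a median of 0.11, mature epithelial genes -0.06, Aire-dependent antigens -0.13, cornified genes -0.09 and Aire neighbours 0.03, none of them called with all 9 arrays. The dendritic list was called in camera without knockout 7, with 0.25 and an adjusted p of 2.43e-05, and had 0.034 without knockout 8 and 0.02 without knockout 9. Cornified genes were called at -0.16 without wild type 1 and at -0.20 without knockout 9, with camera adjusted p-values of 0.0334 and 0.0376, and had -0.026 without wild type 2, -0.0026 without wild type 3, 0.025 without knockout 7 and -0.059 without knockout 8. Without wild type 1, camera also called mature epithelial genes at -0.17 and Aire-dependent antigens at -0.11, with adjusted p-values of 0.0156 and 0.0274. Without wild type 2 these lists had 0.052 and -0.0091, and without knockout 7 the mature list had 0.022. NF-kB targets, cortical epithelial genes and other tissue-restricted antigens had -0.019, -0.087 and -0.073, not called with all 9 arrays. Without wild type 1 camera called them at -0.17, -0.13 and -0.068, with adjusted p-values of 0.0156, 0.0178 and 0.0274. Cortical genes were also called without knockout 8 or 9, and the other antigens without knockout 7. The NF-kB median was 0.091 without wild type 2. Aire neighbours ranged from -0.031 to 0.087 without single arrays.

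In the authors' deposited table, 25 probe sets have a q-value of 0, of which 14 have a gene symbol. All 8 genes called between knockdown and knockout are among them, as are 9 of the 13 called between knockdown and wild type and 7 of the 9 called between knockout and wild type.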
